A study of Rattus norvegicus with 16 samples.

How the data were processed

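MicroRNA was profiled in EDL and soleus muscle of young and old rats on 16 Agilent single-colour (Cy3) rat miRNA arrays, 1 per sample. Per the labels' protocols, total RNA was extracted with a silica-column kit and labelled with the manufacturer's labelling and hybridisation kit. Per the file headers, the deposited intensity values of each spot were made with Agilent Feature Extraction 10.7.3.1 (protocol miRNA_107_Sep09); the submitters' processing notes give the version as 10.7. The array grid was annotated on build rn4, per the file headers. The value column used, gProcessedSignal, is the spot intensity after Feature Extraction's own background treatment, and its values can be negative; no scaling between arrays is recorded in the file headers. The authors' series table held the same values (100% of cells equal), so it was not analysed separately.

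Control spots and spots with outlier flags (3.03% of non-control spots) were left out, and saturated spots would have been kept, of which there were 0. The 13540 non-control spots held 1644 probes of 677 miRNAs, with 5 to 20 spots per probe, which were averaged. A probe counted as well above background on an array if more than 0.5 of its spots carried that flag. Each array was divided by the 75th percentile of the 95 probes that were well above background on all 16 arrays. Scaled values were then raised to a floor of 0.03389 (log2 -4.88), the median over arrays of the lowest scaled signal among probes well above background, and converted to log2. Values at the floor have no order. The floor is a median over arrays. It lay above the lowest signal well above background on every EDL array, and below it on every soleus array. Detected dim signal was therefore raised to the floor only on EDL arrays. On soleus arrays, signal not well above background could stay above the floor. Differences between the muscles in dim miRNAs carry this unequal treatment. The brightest probe represented a miRNA, and no called miRNA had another measured probe of opposite sign. A miRNA was tested if its probe was well above background on 4 or more of the 16 arrays, regardless of group, which left 114. A miRNA well above background on 0 arrays of 1 group was given as an "at least" fold, the brighter group's mean over the dim group's mean of, per array, the higher of its own signal and that array's lowest signal well above background, and no fold where that bound was under 1.

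Groups were taken from the labels. All 4 groups of 4 entered 1 limma model (limma 3.58.1, R 4.3.3) with no covariate. Contrasts were old minus young in each muscle, the difference of these age effects (interaction), and soleus minus EDL at each age. Tests were two-sided with Benjamini-Hochberg adjustment within a comparison at 0.05. Adjusted p-values named in the text are from this limma model. Errors given with log2 differences are limma standard errors and those with group means are SDs. Array brightness was compared with two-sided exact permutation tests, which with 4 against 4 arrays allow no p below 0.0286. The jsonlite 2.0.0, Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6 packages were also used.

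The 27 lists of miRNAs covered striated muscle miRNAs (myomiRs), slow-fibre miRNAs hosted in myosin genes, the Dlk1-Dio3 and H19/Igf2 imprinted loci, leukocyte, erythroid, endothelial, smooth muscle, fibroblast, neural, epithelial and liver markers, NF-kB-linked miRNAs, miRNA families (let-7, miR-29, miR-30, miR-34, miR-181, miR-15/16) and genomic clusters (miR-17-92, miR-23/27/24, miR-322/miR-503, Hox, miR-193b/miR-365, miR-378, miR-221/miR-222, miR-210). Lists with 3 or more tested miRNAs (10 lists) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Fry's PValue tests whether a list's members move, on balance, one way, and its Mixed value whether they change in either direction; neither compares the list with other miRNAs. Lists share members (miR-21 is in the NF-kB and fibroblast lists, and miR-322 in the miR-15/16 and miR-322/miR-503 lists). The only tested slow-fibre member, miR-499, is also in the myomiR list, so slow-fibre counts repeat a myomiR value.

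The miRNAs named are, for each age and muscle comparison, the 8 with the largest rise and the 8 with the largest fall past the threshold (the 10 with the smallest p where fewer than 5 passed), all tested myomiRs and up to 4 members of each list described, and for the interaction the 10 with the smallest p. Names outside that rule are marked in the text as chosen after their values were seen. The design, lists, naming rule and first set of alternative settings were made before the data were examined. That set covered the scaling, background, signal column, probe rule, dim-probe filter, floor, samples in the fit, replicate-number blocks and leaving out each array. Normexp (offset 50) was applied to gMedianSignal, because the files hold no gMeanSignal. Added after the data were seen were a floor 2 times lower, subtraction of negative-control signal, array brightness (log2 of the scaling percentile) as a covariate, scaling to the labelling spike-ins, and leaving out young soleus 7 and 8. No block for slide or scan could be fitted, because all 8 EDL arrays lay on 1 slide, the young soleus arrays on another and the old soleus arrays on another.

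The procedure was tested on simulated data made from the array values with 24 changed miRNAs. In 20 simulations of each comparison, 45% (EDL) and 47.8% (soleus) of miRNAs changed by log2 0.5 with age were recovered, 80.4% and 80.8% at log2 1, and 96.5% and 82.6% at log2 2. For the muscle comparison the shares were 51.6%, 82.1% and 86.8% in young and 47.1%, 85.4% and 86.8% in old rats. Unchanged miRNAs made up 23.3% (EDL age), 17.3% (soleus age), 10.3% (young muscle) and 13.9% (old muscle) of calls, against 4.6%, 4.3%, 2.7% and 4% when the true scaling was used, since changed miRNAs moved the percentile. The muscle comparisons of the real arrays called 49 and 61 miRNAs, more than the 24 changed here. The simulated shares of false calls may therefore not hold for them. With no miRNA changed, 1, 3, 0 and 2 of the 20 simulations made a call. Shifted lists were found in 100% of simulations and unchanged lists in 0%. In these simulations miRNAs varied independently of each other, and the list p-values were unadjusted. Estimated correlations within the lists tested ran from 0.34 to 0.854, so the simulations do not test the list calls under such correlation.

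miRNA names are those of the array design; 113 of the 114 tested names were matched to genes in a RefSeq table of assembly GRCr8, which was used for names and for which genes neighbour each other (within 10000 bases). No coordinates are given, because the array's build differs. No 2 arrays of a group carried duplicated values (at the closest, 44.8% of probes differed by more than 2 spot standard errors). A list was not tested where under 3 of its miRNAs were tested.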

Results

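MicroRNA abundance was profiled in hindlimb muscle of male Fischer (F344) rats on 16 single-colour arrays. The arrays formed 4 groups of 4, taken from EDL (extensor digitorum longus, a predominantly fast-twitch muscle) and soleus (a predominantly slow-twitch muscle) of young rats aged 6 to 7 months and old rats aged 25 to 28 months. The comparisons ask which miRNAs differ with age in each muscle, whether the age effect differs between muscles, and how the muscles differ at each age. The labels do not say explicitly that the arrays are separate animals, so p-values then measure only the spread between these samples, which may be technical. They also do not say whether EDL and soleus samples of the same number came from the same rat, and the main model takes them as unpaired. The number of arrays limits the precision.

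Arrays from soleus were dimmer than arrays from EDL. The 75th percentile of processed signal used for scaling was 589 to 1864 on EDL arrays and 290 to 681 on soleus arrays, and 83 to 138 miRNAs were well above background on EDL arrays against 59 to 86 on soleus arrays. The floor lay above some detected signals on every EDL array and on no soleus array, so muscle differences of dim miRNAs carry this bias. Brightness differed between the muscles by log2 -1.69 in old rats (two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.114) and by -1.16 in young rats (exact p = 0.0857, adjusted p = 0.171). With age it differed by log2 0.27 in EDL (exact p = 0.6) and -0.27 in soleus (exact p = 0.343). A labelling spike-in, dmr_285, ran from 194 to 804 on EDL arrays and from 55.9 to 180 on soleus arrays. The correlations used the geometric mean of dmr_285 and another labelling spike-in, dmr_31a. Across the 8 EDL arrays this mean followed the percentile (log2 values, Pearson r = 0.991, permutation p = 7e-05, adjusted p = 0.00014). Spearman rho was 0.929 (permutation p = 0.002), and r was 0.979 without the 2 arrays farthest from the median. Across the 8 soleus arrays r was 0.906 (permutation p = 0.004, adjusted p = 0.004) and rho 0.714 (permutation p = 0.06), with r = 0.757 without the 2 farthest arrays. Feature Extraction's own check of the labelling spike-in signal put young soleus 7 and 8 and every old soleus array out of range. Every EDL array and young soleus 9 and 10 were in range. Hybridisation spike-in signal was lowest on young soleus 7 (2098) and young soleus 8 (3639), against 5842 to 9784 on the others. The EDL arrays shared 1 slide, while young and old soleus arrays lay on separate slides, so for soleus ages and for both muscle comparisons slide and group cannot be told apart. Within the EDL slide, young and old arrays lay in different columns, so column and age cannot be told apart.

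**Figure D1:**
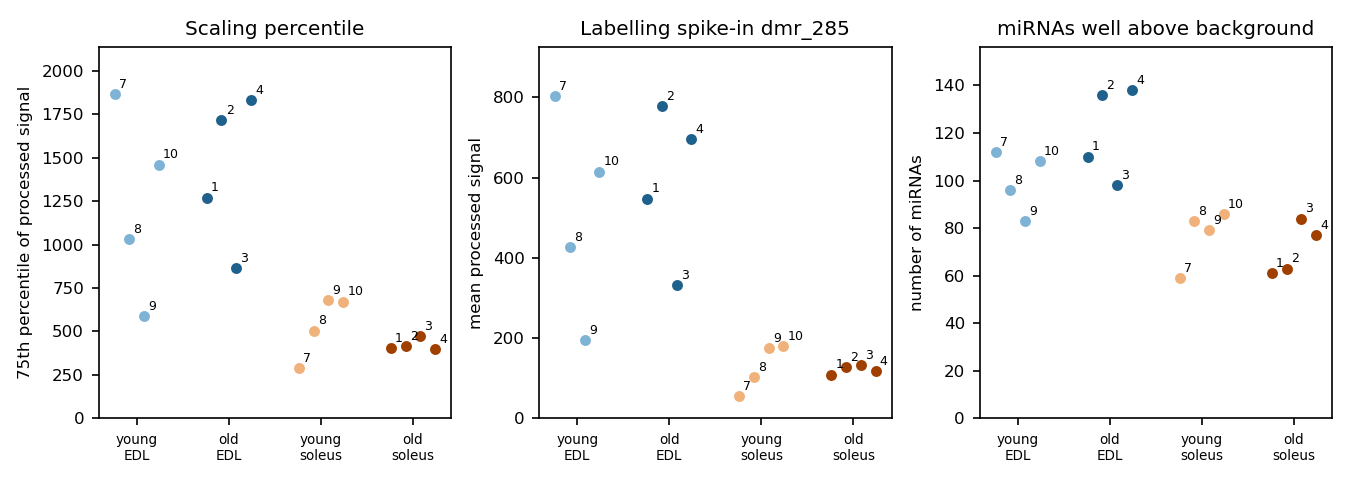
Scaling percentile, labelling spike-in signal (both in processed signal units) and number of miRNAs well above background for each array, with 1 point per array labelled by sample number. The EDL arrays had percentiles of 589 to 1864 and the soleus arrays of 290 to 681.

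In old EDL, miR-206, a muscle-specific miRNA of myogenesis, rose 2.3-fold (log2 1.20, SE 0.10, adjusted p = 3.2e-06, n = 4 per group), from a group mean of 1.05 (SD 0.14) to 2.25 (SD 0.17) relative to the percentile. The miR-29 family, which represses collagens and other matrix transcripts, rose with all 3 members past the threshold: miR-29b 2.12-fold (log2 1.08, SE 0.19), miR-29a 1.53-fold (0.61, SE 0.11) and miR-29c 1.5-fold (0.59, SE 0.16). A p53-induced miRNA, miR-34a, was higher by log2 0.94 (SE 0.13, adjusted p = 0.000364), although the young values lay at the floor on all 4 arrays, so its change is measured from the floor. It was well above background on 3 of those 4 arrays, so the floor replaced detected signal there. miR-21, linked to NF-kB and to fibroblasts, rose 2-fold (SE 0.25 on the log2 scale, adjusted p = 0.0218). The Hox-cluster miRNA miR-196a fell by 0.71 on the log2 scale (SE 0.12, adjusted p = 0.00174).

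Of 114 tested miRNAs, 14 changed with age in EDL, 12 higher and 2 lower, and 26 had an unadjusted p under 0.05. In the simulations of this comparison 23.3% of calls were unchanged miRNAs. The other rises were miR-140* (log2 0.62), miR-92a (0.59), miR-23a (0.37), miR-27a (0.33), let-7d (0.26) and miR-352 (0.35, chosen after its value was seen), and the other fall was miR-103 (-0.27). With normexp background miR-34a, miR-140*, miR-92a and miR-352 turned to -0.04, -0.26, -0.25 and -0.28 and let-7d to -0.04 with the percentile over all probes. These settings moved the median of all miRNAs by -0.37 and -0.23, and all 5 stayed above that median. Groups did not overlap for 14 miRNAs (12.3%, where chance gives 2.86%), of which 11 were called.

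Among lists, 1 of 5 tested myomiRs rose (miR-206), and the 4 others did not pass: miR-133b 0.04, miR-133a -0.06, miR-1 0.00 and miR-499 -0.01. The miR-29 list was the one list called by camera in this comparison (mean log2 0.76, adjusted p = 0.00519), and adjusted p = 0.471 with an estimated correlation; fry gave adjusted p = 0.00257. In the NF-kB list 1 of 3 rose (miR-21) while miR-146a (0.58, adjusted p = 0.19, and 0.38 without young EDL 9) did not pass. Fibroblast miRNAs had 2 of 8 higher (miR-21 and miR-140*), the let-7 family 1 of 8 (let-7d; let-7a at 0.18 did not pass), the miR-17-92 clusters 1 of 5 (miR-92a), and the miR-23/27/24 clusters 2 of 5 (miR-23a and miR-27a; miR-24 at 0.16 did not pass). The Hox list had 1 of 5 lower (miR-196a) and miR-10a-5p at 0.34 (0.23 without young EDL 9) did not pass, and the miR-34 list had its 1 tested member higher. Leukocyte markers miR-150 (0.23, adjusted p = 0.173) and miR-223 (0.37, adjusted p = 0.392) did not pass, nor did the erythroid marker miR-451 (1.19, SE 0.59, adjusted p = 0.256, and 0.65 without old EDL 3), whose values included the floor on 3 young and 2 old arrays. No member of the miR-30 (5 tested), miR-15/16 (5), endothelial (2), smooth muscle (2), miR-378 (2), miR-181 (2), Dlk1-Dio3 (2), H19/Igf2 (1), neural (1), slow-fibre (1) or miR-322/miR-503 (1) lists passed. Of the 114 tested miRNAs 11 lay at the floor on all 16 arrays and could not pass in any comparison, among them the only tested H19/Igf2 member and 1 member each of the endothelial, miR-181 and fibroblast lists. Each of the 11 was well above background on 4 or more arrays, so the floor hid detected signal and they were not measured as unchanged. Adjusted over the list alone, 1 of the 2 members of the miR-193b/miR-365 list rose, against 0 over all tested miRNAs, and the counts of all other lists were equal both ways.

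This comparison lies within 1 slide, but young and old EDL arrays lay in different slide columns. Column and age therefore cannot be told apart for any of the 14 calls. A model of the EDL arrays alone called 11 miRNAs (8 higher, 3 lower), 10 of them among the 14. The count fell to 0 with the percentile taken over all probes, to 0 with no scaling (miR-206 at 0.89 and 1.47 there) and to 1 with normexp background correction, and it ran from 7 to 16 when single arrays were left out. Quantile normalisation gave 22 with another balance of directions (10 higher, 12 lower).

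**Figure D2:**
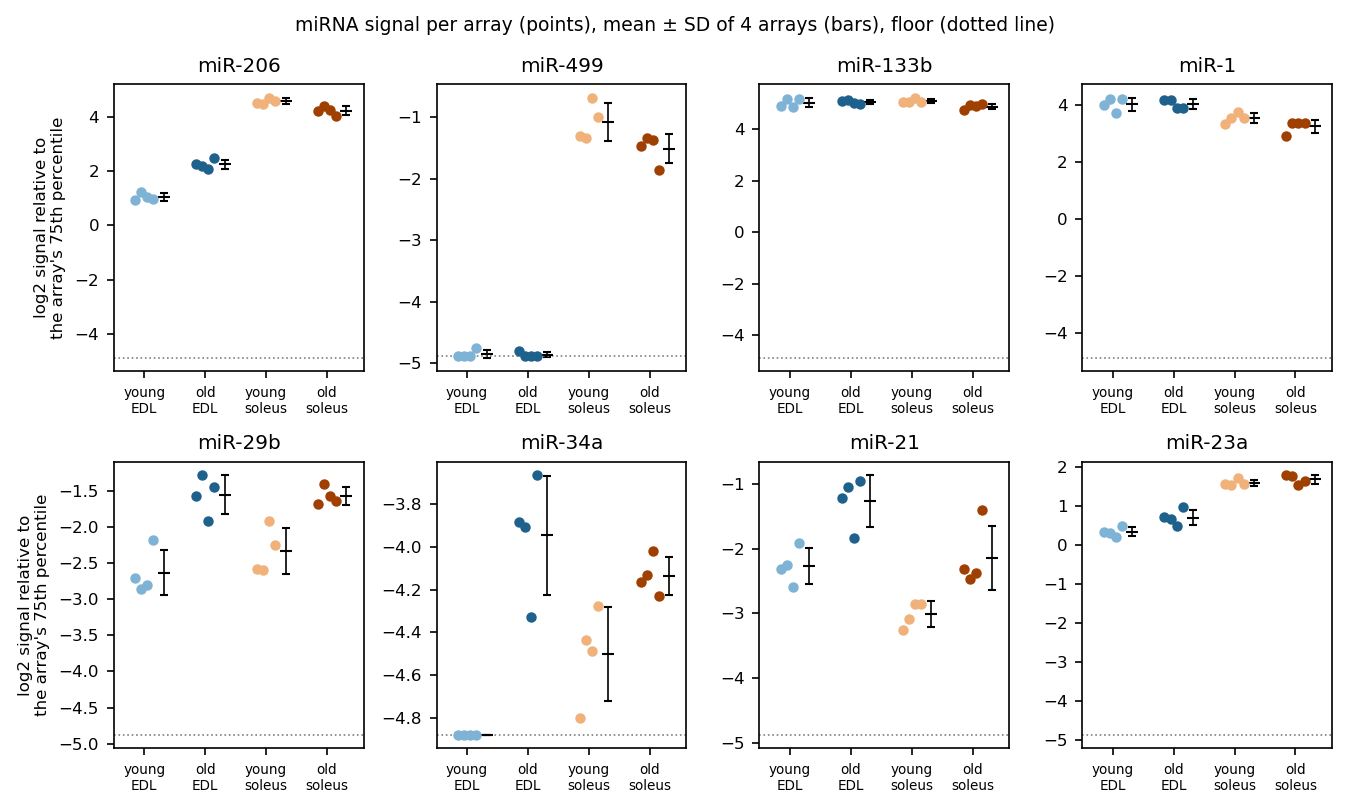
Log2 signal relative to the 75th percentile of each array for 8 miRNAs, 1 point per array and 4 arrays per group, with bars for the mean and SD and a dotted line for the floor (-4.88). miR-206 had mean values of 1.05 in young and 2.25 in old EDL, and miR-499 lay at the floor on 3 of 4 EDL arrays at each age.

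In old soleus, the Hox-cluster miRNA miR-196a fell by 0.80 on the log2 scale (SE 0.12, adjusted p = 0.00155, n = 4 per group), and the miR-30 family member miR-30c fell by 0.44 (SE 0.10, adjusted p = 0.0384). On the old soleus arrays miR-196a was well above background on 2 of 4. miR-214, expressed in mesenchyme, rose by log2 0.73 (SE 0.17, adjusted p = 0.0384) and miR-29b rose 1.7-fold (log2 0.76, SE 0.19, adjusted p = 0.0384). miR-206 was at -0.34 (SE 0.10, adjusted p = 0.0636) and did not pass.

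These 4 miRNAs (2 higher, 2 lower) were the only calls of 114, with 35 at an unadjusted p under 0.05. Groups did not overlap for 25 miRNAs (21.9%, where chance gives 2.86%). Below the threshold were miR-128 (-0.46), miR-21 (0.86), miR-16 (-0.37), miR-30e (-0.54), each with adjusted p = 0.0636, and miR-195 (-0.47, adjusted p = 0.0647), as was miR-34a (0.36, adjusted p = 0.102, chosen after its value was seen). Both miR-29a (0.16) and miR-29c (0.04) also did not pass.

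No myomiR passed singly over all tested miRNAs, with miR-499 at -0.43 (SE 0.14), miR-1 at -0.28 (-0.17 without old soleus 1), miR-133a at -0.22 and miR-133b at -0.21, while 4 fell when adjusted over the list alone. The list was lower in camera (mean -0.30, adjusted p = 0.0119), with adjusted p = 0.575 with an estimated correlation, and by fry (adjusted p = 0.0411). The fibroblast list had 1 of 8 higher (miR-214) and the others did not pass, including miR-140* (0.37) and miR-22 (-0.32). That list was higher in camera (mean 0.31, adjusted p = 0.0431; adjusted p = 0.575 with an estimated correlation) and not by fry (adjusted p = 0.165), and 5 rose and 1 fell adjusted over the list alone. The miR-30 family had 1 of 5 lower and miR-30a at -0.29 not passed. Camera gave adjusted p = 0.0431 (mean -0.29), adjusted p = 0.575 with an estimated correlation, fry adjusted p = 0.163, and 2 fell adjusted over the list alone. Of the miR-29 family 1 of 3 rose (miR-29b) and of the Hox list 1 of 5 fell. In the miR-15/16 family 0 of 5 passed and 2 fell adjusted over the list alone. In the NF-kB list 0 of 3 passed and 1 rose over the list alone. The neural (miR-128), slow-fibre (miR-499) and miR-34 lists, with 1 member each, had 0 past the threshold and 1 over the list alone. Leukocyte markers miR-223 (0.38, and 0.61 without young soleus 7 or 0.23 without young soleus 9) and miR-150 (-0.19), and the let-7 (8 tested, let-7b at 0.15), miR-17-92 (5), miR-23/27/24 (5), endothelial (2), smooth muscle (2), miR-378 (2), miR-181 (2), miR-193b/miR-365 (2), Dlk1-Dio3 (2), erythroid (1), H19/Igf2 (1) and miR-322/miR-503 (1) lists had no member past the threshold either way.

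The count of 4 rested on array choice and scaling. It rose to 26 without young soleus 7 (the array with the lowest hybridisation signal) and stood at 1 or 2 without any other single array, and it was 16 with array brightness as a covariate (miR-21, miR-34a, miR-128, miR-16, miR-30e, miR-195 and miR-140* then passed). It was 0 with the percentile over all probes, without scaling or with normexp, and 45 (1 higher, 44 lower) with scaling to the labelling spike-ins.

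**Figure D3:**
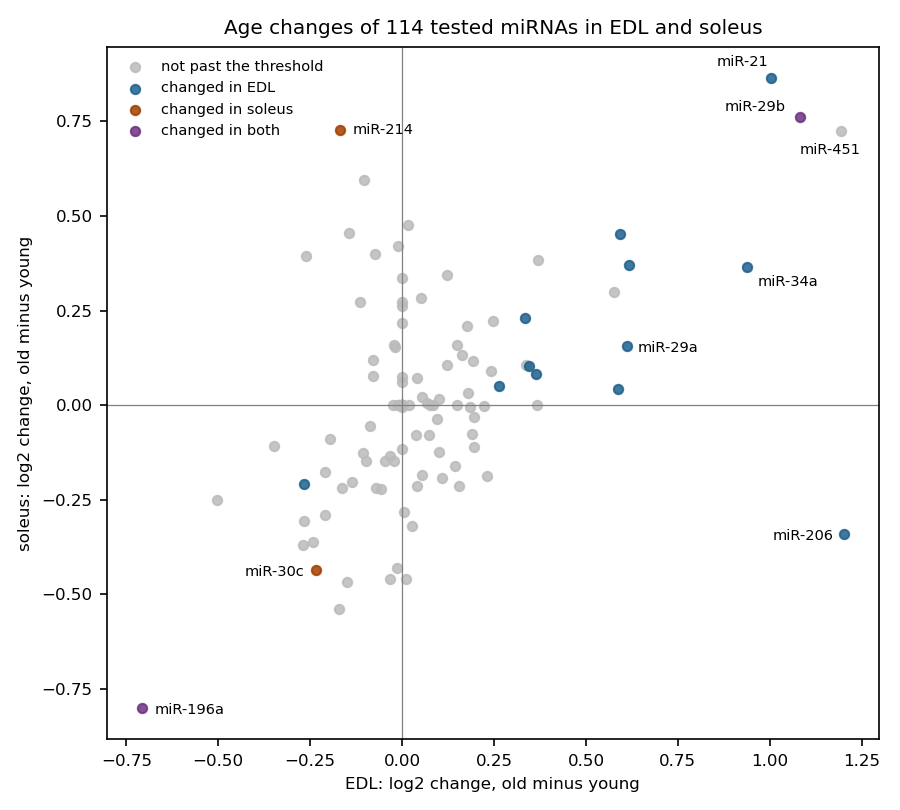
Log2 change with age (old minus young) of 114 tested miRNAs in EDL (horizontal axis) and soleus (vertical axis), coloured by whether the change passed the threshold. miR-29b and miR-196a passed in both muscles, and miR-206 stood at 1.20 in EDL and -0.34 in soleus.

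The age effect of miR-206 differed between the muscles: soleus minus EDL was log2 -1.54 (SE 0.14, adjusted p = 9.79e-06), from 1.20 in EDL and -0.34 in soleus. It was the only miRNA past the threshold in the interaction, with 13 at an unadjusted p under 0.05. The next miRNAs by p did not pass: miR-214 (0.90, adjusted p = 0.159), miR-34a (-0.57), miR-150 (-0.42), miR-199a-3p (0.66) and let-7d (-0.21) with adjusted p = 0.244, miR-29a (-0.46, adjusted p = 0.246), miR-128 (-0.47), miR-29c (-0.54) and miR-193 (-0.37, at the floor on all 8 soleus arrays, so that this restates its EDL change).

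Of 5 tested myomiRs 1 passed the interaction and 4 did not, among them miR-499 (-0.42), miR-1 (-0.29, and -0.17 without old soleus 1 or -0.18 without young EDL 9), miR-133b (-0.26) and miR-133a (-0.16), these 4 chosen after their values were seen. The list was lower in camera (mean -0.53, adjusted p = 0.00308), with adjusted p = 0.402 with an estimated correlation. Adjusted over the list alone, 1 myomiR, 2 miR-29 members, and 1 each of the leukocyte, neural and miR-34 lists had a lower and 2 fibroblast miRNAs a higher age effect in soleus. For the fibroblast list the median (-0.04) and mean (0.17) differed in sign, and for the let-7 (mean -0.03) and Hox (mean -0.09) lists the camera direction was up. The age effects in the muscles had r = 0.495 and rho = 0.396 across miRNAs, which are not independent replicates, and 56 of 114 miRNAs, and 13 of the 14 EDL calls, had the same sign in both muscles. The 114 include 20 miRNAs at the floor on all EDL arrays and 19 on all soleus arrays (11 on both). Their change there was 0, so they could not share a sign. The calls shared miR-29b among those higher (expected 0.21 by chance) and miR-196a among those lower (expected 0.04). The interaction had 0 calls with the percentile over all probes or without scaling, where the miR-206 interaction stood at -1.61 and -2.08. It had 31 (all lower) with spike-in scaling and 9 without young soleus 7, and miR-199a-3p also passed with array brightness as a covariate (0.81).

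Between the muscles in young rats, miR-499, encoded within a slow myosin gene, was higher in soleus by log2 3.77 (SE 0.14, adjusted p = 7.14e-11, n = 4 per group) with EDL values at the floor on 3 of 4 arrays, and miR-206 was 11.5-fold higher (log2 3.52, SE 0.10, adjusted p = 6.56e-12). Of the 5 tested miRNAs of the miR-23/27/24 clusters 4 were higher in soleus, miR-23a 2.39-fold (log2 1.26, SE 0.10), miR-27a 2.08-fold (1.06, SE 0.10), miR-24 (0.70) and miR-23b (0.40), and 1 did not pass. The latter, miR-27b (0.24, chosen after its value was seen), passed with array brightness as a covariate (0.493). Camera called the list (mean 0.73, adjusted p = 0.0012), with adjusted p = 0.652 with an estimated correlation. The list turned to a mean of -0.29 with the percentile over all probes and -0.43 without scaling, which moved the median of all miRNAs by -0.85 and -0.91. With that median subtracted, which is itself a scaling between arrays, the list stood at 0.56 and 0.48. Lower in soleus were miR-181a (-1.04), miR-100 (-0.99), miR-1949 (-0.94), miR-199a-3p (-0.86), miR-99a (-0.81), miR-30a (-0.76), miR-21 (-0.74) and miR-30a* (-0.72). miR-92a was at least 1.16-fold lower in soleus, where it was well above background on 0 arrays. With array brightness as a covariate the calls of miR-21 (-0.31) and miR-92a (-0.51) were lost.

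In all, 49 miRNAs differed in young rats (22 higher and 27 lower in soleus), with 58 at an unadjusted p under 0.05, and groups did not overlap for 40 (35.1%, where chance gives 2.86%). The balance of directions rested on the scaling, with 61 higher and 3 lower with spike-in scaling and 2 higher and 61 lower without scaling. Other rises were miR-652* (1.33), miR-2985 (1.09), miR-500 (1.04) and miR-652 (1.02), of which miR-2985 lay at the floor on 3 of 4 EDL arrays. The calls of miR-652*, miR-2985 and miR-500 were lost with array brightness as a covariate (0.94, 0.34 and 0.25), and miR-500 and miR-652 turned to -0.11 and -0.14 without scaling. Of 5 tested myomiRs 2 were higher (miR-499, miR-206) and 2 lower (miR-133a -0.61, miR-1 -0.49, turning to 0.01 and 0.12 with spike-in scaling, and miR-1 lost at -0.27 with the brightness covariate), with miR-133b at 0.07 not passed. The camera test of myomiRs was not called (adjusted p = 0.302), while fry's Mixed adjusted p was 0.00021.

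Among the lists of other cell types, 2 of 2 smooth muscle markers were lower (miR-145 -0.67, miR-143 -0.37, the latter turning to 0.24 with spike-in scaling), 5 of 8 fibroblast miRNAs were lower (miR-199a-5p -0.71 and miR-214 -0.66 among them), and leukocyte markers split, miR-223 higher (0.95, turning to -0.07 with the percentile over all probes and -0.21 without scaling) and miR-150 lower (-0.31, turning to 0.30 with spike-in scaling). The brightness covariate ended the calls of miR-143 (-0.09), miR-199a-5p (-0.46), miR-214 (-0.46), miR-223 (0.36) and miR-150 (-0.12). The Hox list had 2 of 5 higher, miR-10b (0.65) and miR-196a (0.50), which turned to -0.37 and -0.51 with the percentile over all probes and to -0.51 and -0.65 without scaling. Within the pair hosted in Ppargc1b, miR-378* was higher (0.45, turning to -0.56 and -0.70 in those settings) and miR-378 lower (-0.64). In the miR-30 family 2 of 5 were lower, in the NF-kB list 1 of 3 (miR-21), and 1 each of the miR-181 (2 tested), miR-17-92 (5), miR-15/16 (5) and miR-193b/miR-365 (2, miR-365 at -0.67) lists. In the let-7 family 1 was higher and 1 lower of 8, and 1 was higher in each of the Dlk1-Dio3 (2), neural (1), miR-34 (1) and slow-fibre (1) lists. Of these, the brightness covariate ended the lower calls of let-7 and NF-kB, 1 of 2 in the miR-30 family, the Dlk1-Dio3 call and, in all, 4 of 5 in the fibroblast list. No miR-29 (3 tested, miR-29b at 0.30, and 0.45 without young EDL 10 or 0.16 without young soleus 9, and miR-29c at -0.15, chosen after their values were seen), endothelial (2), erythroid (1), H19/Igf2 (1) or miR-322/miR-503 (1) member passed. With the brightness covariate miR-29b passed (0.685). Adjusted over the list alone, the counts were 5 of 5 for miR-23/27/24, 1 of 2 lower for endothelial markers and 2 of 2 lower for miR-193b/miR-365, and equal to those above for the other lists.

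In old rats, soleus exceeded EDL in miR-499 by log2 3.35 (SE 0.14, adjusted p = 6.08e-10, with EDL values at the floor on 3 of 4 arrays) and in miR-206 by 1.98 (SE 0.10, adjusted p = 4.07e-09), 3.94-fold. Of the miR-23/27/24 clusters 4 of 5 were higher (miR-23a 0.98, miR-27a 0.95, miR-24 0.67, miR-23b 0.30). The other, miR-27b (0.14, chosen after its value was seen), passed with the brightness covariate (0.512). Camera called the list (mean 0.61, adjusted p = 0.00419), with adjusted p = 0.785 with an estimated correlation. The list turned to -0.48 with the percentile over all probes and -1.08 without scaling, where the median of all miRNAs moved by -1.04 and -1.56. Lower in soleus were miR-100 (-1.14), miR-181a (-1.08), miR-99a (-1.04), miR-1949 (-0.96), miR-365 (-0.91), miR-21 (-0.88), miR-30a* (-0.84) and miR-30a (-0.84). With normexp background, which moved the median of all miRNAs by 0.47, miR-100, miR-181a, miR-1949 and miR-30a* turned to 0.01, 0.11, 0.06 and 0.03. The miR-30 family, with 5 of 5 members lower (miR-30b-5p -0.70), had a camera adjusted p = 0.184 and a fry adjusted p of 0.00168. With the brightness covariate 2 of the 5 passed (miR-30a at -0.63) and 3 did not (miR-30b-5p at -0.46). That covariate also ended the calls of miR-21 (-0.25) and miR-30a* (-0.56).

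In old rats 61 miRNAs differed (24 higher and 37 lower in soleus), with 67 at an unadjusted p under 0.05, and groups did not overlap for 60 (52.6%, where chance gives 2.86%). This balance too rested on the scaling, with 32 higher and 17 lower with spike-in scaling and 1 higher and 92 lower without scaling. Further rises were miR-2985 (1.48), miR-3588 (1.37), miR-3085 (1.31), miR-652* (1.30), miR-500 (1.28) and miR-652 (1.24), with miR-2985 and miR-3085 at the floor on 3 of 4 EDL arrays. None of these 6 passed with array brightness as a covariate (miR-2985 0.38, miR-3588 -0.28, miR-3085 0.61, miR-652* 0.74, miR-500 0.12, miR-652 0.64), and miR-3588, miR-652*, miR-500 and miR-652 turned to -0.32, -0.39, -0.41 and -0.46 without scaling. Of the myomiRs 2 were higher and 2 lower (miR-133a -0.77, miR-1 -0.77, the latter lost at -0.46 with the brightness covariate), and miR-133b (-0.19) did not pass; the list's median (-0.19) and mean (0.72) differed in sign, and camera gave adjusted p = 0.562. miR-25 was at least 1.17-fold lower, with 0 old soleus arrays well above background, and its call was lost with the covariate (-0.04).

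In old rats smooth muscle markers were lower in 2 of 2 (miR-145 -0.79, turning to 0.28 with normexp, and miR-143 -0.74), 3 of 8 fibroblast miRNAs were lower, and miR-29a (-0.45) and miR-29c (-0.69) were lower of 3. With the brightness covariate miR-143 (-0.32), miR-29a (-0.06) and miR-29c (-0.29) no longer passed, nor did miR-223 (0.10) and miR-196a (0.55) named next, nor any of the 3 fibroblast miRNAs. Of the leukocyte markers miR-223 was higher (0.96, turning to -0.12 with the percentile over all probes and -0.73 without scaling) and miR-150 lower (-0.73). miR-378* was higher (0.42, turning to -0.66 and -1.27 in those settings) and miR-378 lower (-0.41), and miR-196a was the 1 of 5 Hox miRNAs past the threshold (0.41, turning to -0.65 and -1.23). The miR-196a rise also turned direction with negative-control signal subtracted. In the Dlk1-Dio3 list both tested miRNAs were higher, of 83 on the array, 81 of which were never well above background; miR-494 (1.16, chosen after its value was seen) turned to -0.53 without scaling and was lost at 0.09 with the brightness covariate. The miR-17-92 list had 3 of 5 lower, the miR-193b/miR-365 list 2 of 2, the let-7 family 1 higher and 2 lower of 8, NF-kB 1 of 3 lower, and the endothelial (2), miR-181 (2) and miR-15/16 (5) lists 1 lower each. The brightness covariate ended all 3 calls of the miR-17-92 and all 3 of the let-7 lists, both Dlk1-Dio3 calls, the endothelial and NF-kB calls and 1 of 2 in the miR-193b/miR-365 list. A lost call was not always a smaller difference: let-7b stood at 0.25 with the covariate against 0.22 without it, while miR-25 stood at -0.04. Slow-fibre had 1 of 1 higher, and no erythroid (1), H19/Igf2 (1), neural (1), miR-34 (1) or miR-322/miR-503 (1) member passed. Adjusted over the list alone, 3 myomiRs and 2 NF-kB miRNAs were lower, and 2 fibroblast and 1 let-7 miRNAs were lower, the other counts being equal. For the let-7 family the mean (-0.08) and the camera direction (up) differed in sign.

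Effects in young and old rats had r = 0.911 across miRNAs, and the calls shared 17 miRNAs higher in soleus (4.63 expected by chance) and 24 lower (8.76 expected), with 0 in opposite directions. With array brightness as a covariate, 7 of the 17 (miR-206, miR-499, miR-23a, miR-23b, miR-24, miR-27a and miR-378*) and 11 of the 24 (among them miR-100, miR-181a, miR-99a, miR-1949, miR-30a and miR-133a) passed at both ages, and the counts were 32 in young and 24 in old rats. Normexp background left 5 and 7 calls. The 27 lists included 4 with no tested miRNA: epithelial (14 on the array, none well above background on any array), liver (2, none), miR-221/miR-222 (2) and miR-210 (1, on 3 arrays). miR-208b, in the myomiR and slow-fibre lists, was well above background on 0 arrays.

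**Figure D4:**
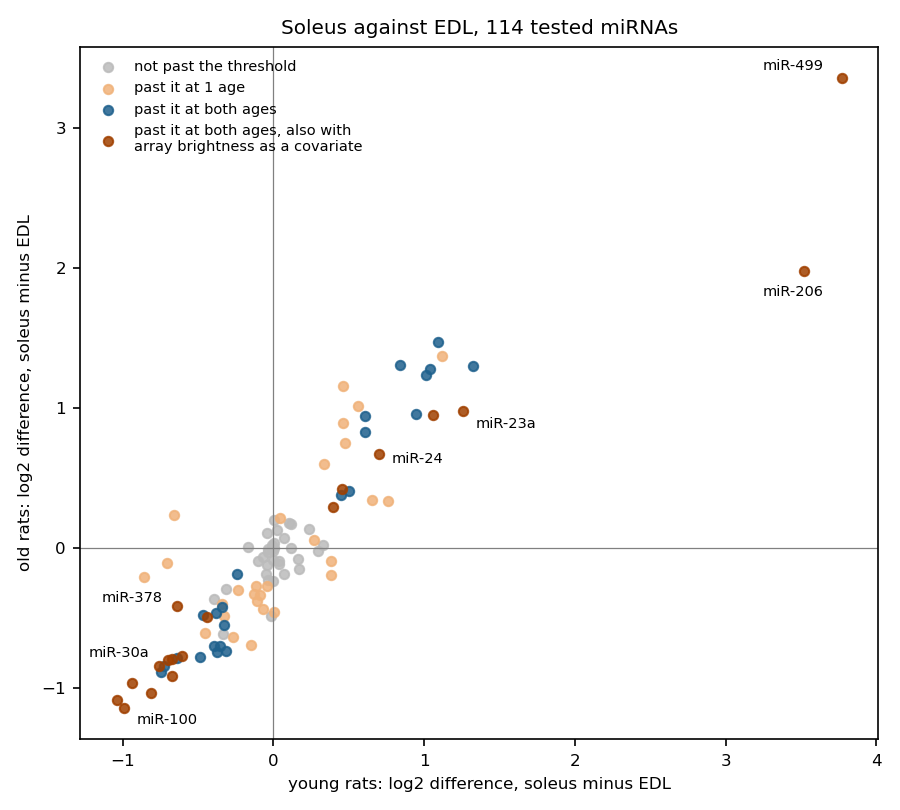
Log2 difference soleus minus EDL of 114 tested miRNAs in young (horizontal axis) and old rats (vertical axis), coloured by calls at both ages and by whether they held with array brightness as a covariate. miR-499 (3.77 and 3.35) and miR-206 (3.52 and 1.98) stood farthest from 0; the higher calls of miR-23a and miR-24 turned to -0.10 and -0.41 in old rats with the percentile over all probes.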

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

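The tests of explanations for miR-206, for the rises in old soleus and for the miR-29 family, miR-34a and miR-21 were chosen only after the results were seen, while the splits and relabellings of arrays were chosen before.

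The age effect of miR-206 had opposite signs in the muscles (1.20 in EDL, -0.34 in soleus, where it did not pass), a difference of -1.541. Soleus tissue in the old EDL samples would need a share of 16.1% and would raise miR-499 by 1.31, while miR-499 changed by -0.013 (SE 0.14), which argues against it, although miR-499 lay at the floor on 3 of 4 EDL arrays at each age. A change under the floor would not be seen, and miR-499 was well above background on 2 young and 4 old EDL arrays. Array brightness is also argued against, since miR-206 in EDL stood at 1.187 (SE 0.10) with brightness as a covariate. Position on the slide cannot be told apart from age, because 0 slide columns held EDL arrays of both ages. The miR-206 interaction passed with and without brightness (-1.51 and -1.54) and did not pass with the percentile over all probes (-1.61) or without scaling (-2.08), and its biological cause was not tested.

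The 24 rises in old soleus over old EDL included 16 miRNAs never at the floor. For 8 of them (let-7b, miR-1224, miR-223, miR-345-5p, miR-3588, miR-494, miR-500 and miR-652) brightness within soleus arrays predicted more than 0.5 of the rise, and the slope within EDL arrays predicted a median of 0.695 against 1.09 observed. It predicted more than 0.5 of the rise for 5 of the 8 (miR-1224, miR-223, miR-3588, miR-494 and miR-500), for which array brightness may account, and less for miR-345-5p and miR-652. For let-7b it predicted a fall (-0.128), and the change was 0.25 with the covariate against 0.22 without. For the other 8 (miR-206, miR-23a, miR-23b, miR-24, miR-27a, miR-378*, miR-196a and miR-652*) the median prediction from EDL arrays was -0.221 against 0.81 observed. With the covariate 6 calls were kept (all but miR-196a and miR-652*). The set was chosen by the soleus slopes, which the covariate also uses, so this is partly built in. The slopes within EDL arrays ran from -0.051 (miR-378*) to 0.186 (miR-23a) for these 6. Such slopes predict no rise or a small one on dimmer arrays, which argues against brightness for these 6. The slopes on brightness predicted no rise for miR-196a (0.10 in EDL and 0.04 in soleus), whose change grew from 0.41 to 0.55 with the covariate although the call was lost. With negative-control signal subtracted, however, the miR-196a rise turned to a fall. It was well above background on 2 of 4 old soleus arrays, so background in dim signal stays open for miR-196a. Brightness stays open for miR-652*, with 1.24 predicted of 1.30 from the slope in EDL (-0.735), while the slope in soleus had the opposite sign (0.556). Slide cannot be told apart from muscle for either set, since 0 slides held arrays of both muscles. A difference between the muscles themselves was not tested apart from slide.

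The miR-29 family, miR-34a and miR-21 rose together in old EDL. Brightness is argued against, since their median change with brightness as a covariate was 0.878 (0.94 without it). Leukocyte RNA cannot be told from the tables, since miR-150 was at 0.231 and miR-223 at 0.37 and neither passed, while miR-223 passed with brightness as a covariate (0.50). Position on the slide cannot be told apart from age for these rises either. Whether an age effect on matrix-linked or stress-linked miRNAs underlies the rises was not tested.

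Splitting the 8 arrays of a comparison into other groups of 4 shows how often such counts arise. For age in EDL, 2 of 35 splits (the real one included) gave 14 or more calls, with 20 as the highest other, and for age in soleus 3 of 35 gave 4 or more, with 12 as the highest other, so chance cannot be excluded for either count. The soleus split with 12 calls separated arrays with percentiles of 290 to 414 from arrays with 472 to 681. The other splits as large overlapped in percentile: 589 to 1864 against 1270 to 1830 in EDL (20 calls) and 290 to 472 against 400 to 681 in soleus (6 calls). Each of these splits differed from the real one by an exchange of 1 young and 1 old array, so it could carry part of any age effect. For the interaction 10 of 100 relabellings gave 1 or more, with 7 as the highest other, so chance cannot be excluded for the count. For the muscle comparisons the real split was the only 1 of 35 at its count, 49 in young rats (highest other 14) and 61 in old rats (highest other 1). A share of 1 in 35 is the smallest that these splits can give. It argues against a chance division of the arrays without excluding it, and slide cannot be told apart.

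Dixon's test for a single array apart from its group marked 24 of 235 groups, where chance marks about 1 in 20 (11.8). At the floor, where 3 of 4 arrays were equal and the value is 1 by construction, were miR-2985 (young EDL 9, old EDL 3), miR-3085 (young EDL 9, old EDL 3), miR-451 (young EDL 10) and miR-499 (young EDL 10, old EDL 1). Of the others, 4 fell on young soleus 7: miR-352 (0.895, low), miR-146a (0.831, low), miR-500 (0.86, high) and miR-3085 (0.835, high). Old soleus 1 was low in miR-1 (0.956) and miR-133a (0.907), and old soleus 4 was low in miR-128 (0.832) and high in miR-21 (0.846) and miR-92a (0.943). The rest were let-7d (0.873) and miR-25 (0.866) low on young EDL 9, miR-100 low on old EDL 3 (0.874), miR-196a low (0.898) and miR-92a high (0.866) on old EDL 4, miR-1949 high on old soleus 2 (0.918), and miR-133b (0.896) and miR-378* (0.886) high on young soleus 9. All arrays were kept, and the causes were not tested.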

How the results depend on the processing

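The alternatives chosen only after the data were seen were the lower floor, the negative-control subtraction, the brightness covariate, spike-in scaling and leaving out young soleus 7 and 8. Not run were the series table (equal to the values used), blocks for slide and scan (which hold the groups apart), and, for list shifts, the replicate blocks and the models of only the groups compared. Normexp used gMedianSignal, since gMeanSignal is absent. Among named miRNAs and lists 66 values turned direction, 53 of them under the 3 scaling alternatives given next (4 of these are values of the miR-23/27/24 list). Relative to the median of all miRNAs 48 of these 53 kept the main direction. The 5 others were values of miR-133b, let-7c and miR-29c in the muscle comparisons whose main values did not pass. Subtracting that median is itself a scaling, so this return is partly built in and does not show that directions hold under any scaling. Where no cause is given, the cause was not tested.

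With the percentile over all probes, which lay at 0.78 to 6.38 signal units, under the negative controls (6.76 to 11.33), the counts were 0 (EDL age), 0 (soleus age), 0 (interaction), 53 (young muscle; 2 higher, 51 lower) and 63 (old muscle; 1 higher, 62 lower), with the median of all miRNAs at -0.234, -0.239, -0.106, -0.85 and -1.038. let-7d turned to -0.045 in EDL. In young muscle miR-652 turned to -0.002, miR-24 to -0.317, miR-23b to -0.62, miR-378* to -0.564, miR-223 to -0.071, miR-196a to -0.513, miR-10b to -0.365 and the miR-23/27/24 list to -0.287. In old muscle miR-23a turned to -0.105, miR-27a to -0.129, miR-24 to -0.412, miR-23b to -0.786, miR-378* to -0.659, miR-223 to -0.121, miR-196a to -0.647, miR-1224 to -0.062, miR-214 to -0.844, let-7c to -1.058 and the miR-23/27/24 list to -0.475.

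Without scaling, which leaves array brightness in the values, the counts were 0 (EDL age), 0 (soleus age), 0 (interaction), 63 (young muscle; 2 higher, 61 lower) and 93 (old muscle; 1 higher, 92 lower), with the median of all miRNAs at 0.279, -0.17, -0.583, -0.911 and -1.564. In young muscle miR-27a turned to -0.1, miR-500 to -0.114, miR-652 to -0.141, miR-133b to -1.087, miR-24 to -0.456, miR-23b to -0.759, miR-378* to -0.703, miR-223 to -0.21, miR-196a to -0.652, miR-10b to -0.505 and the miR-23/27/24 list to -0.426. In old muscle miR-3588 turned to -0.321, miR-652* to -0.387, miR-500 to -0.41, miR-652 to -0.455, miR-23a to -0.715, miR-27a to -0.739, miR-24 to -1.022, miR-23b to -1.396, miR-378* to -1.269, miR-223 to -0.731, miR-196a to -1.229, miR-494 to -0.531, miR-1224 to -0.672, miR-214 to -1.454, let-7c to -1.668 and the list to -1.085.

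Scaled to labelling spike-ins, the counts were 8 (EDL age), 45 (soleus age; 1 higher, 44 lower), 31 (interaction; all lower), 64 (young muscle; 61 higher, 3 lower) and 49 (old muscle; 32 higher, 17 lower), with the median of all miRNAs at -0.19 in soleus age, -0.284 in the interaction and 0.318 in young muscle. In young muscle miR-1 turned to 0.124, miR-133a to 0.006, miR-143 to 0.24, miR-150 to 0.299, let-7c to 0.604 and miR-29c to 0.466.

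Normexp, which adds an offset of 50 that is a larger share of signal on dim arrays, left 1 (EDL age), 0 (soleus age), 5 (young muscle) and 7 (old muscle; 4 higher, 3 lower) calls, with the median of all miRNAs at -0.373, 0.145, -0.014 and 0.465. In EDL with age miR-34a turned to -0.042, miR-140* to -0.256, miR-92a to -0.247 and miR-352 to -0.281. In old muscle miR-100 turned to 0.01, miR-181a to 0.111, miR-1949 to 0.055, miR-30a* to 0.033, miR-145 to 0.275 and miR-25 to 0.374. With negative-control signal subtracted EDL age had 8 calls (8 higher, 0 lower), and miR-196a in old muscle turned to -0.123. With brightness as a covariate soleus age had 16, the interaction 2, young muscle 32 and old muscle 24 calls, and in old muscle miR-3588 turned to -0.28 and miR-1224 to -0.16. In the interaction miR-199a-3p then passed (0.81).

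Quantile normalisation gave 22 (EDL age; 10 higher, 12 lower), 12 (soleus age; 4 higher, 8 lower) and 3 (interaction) calls. gTotalGeneSignal gave 6 (EDL age), 10 (soleus age; 2 higher, 8 lower) and 4 list shifts against 7. The mean over probes left 1 call in soleus age. With no filter on dim probes there were 7 (EDL age), 1 (soleus age) and 32 (young muscle) calls and 28 list shifts, because every list member on the array then enters. Requiring signal above background on all 4 arrays of a group gave 10 in soleus age, and on all 16 arrays 9 (EDL age), 8 (soleus age), 39 (old muscle) and 4 list shifts. A floor 2 times higher gave 1 in soleus age and 2 in the interaction, and a floor 2 times lower 8 and 2.

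Leaving out single arrays moved EDL age between 7 and 16 (7 without young EDL 7, young EDL 8, old EDL 1 or old EDL 4, and 9 without young EDL 9), soleus age between 1 and 26 (26 without young soleus 7, 1 or 2 without any other), the interaction between 1 and 9 (9 without young soleus 7, 2 without young EDL 10 or old EDL 3), young muscle between 40 and 54, old muscle between 52 and 64 and list shifts between 5 and 8. Without young soleus 7 and 8 soleus age had 19 calls and the interaction 12. Sample numbers as a block (paired by number) gave 2 calls in the interaction, 39 in young and 61 in old muscle when fixed. As a random block (consensus correlation -0.06) they gave 48 in young and 59 in old muscle. The labels use the same numbers in both muscles, and whether a number marks the same animal cannot be told from the values. Correlations between the muscles of a number ran from -0.562 to 0.581, with 4 of 8 over 0.1. Of the 8 samples 2 matched their own number best.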

Other observations

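The brightness covariate, the comparison with the median of all miRNAs and the neighbouring genes named below were chosen only after the results were seen, while the splits and relabellings of arrays were chosen before.

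Of some miRNAs encoded next to each other, 1 passed and the other did not; the differences between neighbours were not tested. Mir206 and Mir133b are neighbours, yet miR-206 rose by 1.20 in old EDL and was 3.52 and 1.98 higher in young and old soleus, while miR-133b stood at 0.04, 0.07 and -0.19 and did not pass. Mir99a neighbours Mirlet7c1, and miR-99a was lower in soleus (-0.81 in young and -1.04 in old rats) while let-7c stood at -0.01 and 0.02 and did not pass, and its direction was not kept under other scalings, even relative to the median of all miRNAs. In old rats miR-29c was lower in soleus (-0.69, a call lost at -0.29 with the brightness covariate) and its neighbour miR-29b did not pass (-0.02). Each of let-7c, miR-29b and miR-24 has a pair of genes, so its level is not that of 1 neighbour alone. Other neighbours moved together, as did miR-23a, miR-27a and miR-24 (1.26, 1.06 and 0.70 higher in young soleus, where miR-27a and miR-24 turned to -0.10 and -0.46 without scaling) and miR-133a and miR-1 (-0.77 and -0.77 in old soleus). With the brightness covariate the old muscle call of miR-1 was lost (-0.46) and that of miR-133a was kept.

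miR-199a-3p and miR-214, from neighbouring genes, were lower in soleus of young rats (-0.86 and -0.66) and did not pass in old rats (-0.20, or -0.09 without old EDL 4, and 0.24, or 0.12 without old soleus 4). Their interactions with age (0.66 and 0.90) did not pass, while with brightness as a covariate miR-199a-3p passed (0.81) and miR-214 did not (0.99), so a change of the muscle difference with age stays unsettled for them. The call of miR-214 in young rats was lost with that covariate (-0.46).

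Amounts of mature miRNA from neighbouring genes could differ through processing or turnover, which these arrays do not measure. Brightness is not a likely source for miR-206, whose rise in EDL was 1.187 with brightness as a covariate. Chance is not excluded for the age counts (2 of 35 splits in EDL and 3 of 35 in soleus) or the interaction count (10 of 100), and the muscle counts cannot be told apart from slide.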
